A study of Mus musculus with 24 samples.

How the data were processed

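Bulk RNA sequencing was available for 24 libraries of mouse Achilles tendon, pulverised and extracted as total RNA, from wildtype and AMPKcKO animals of both sexes at 1 and 3 months with cage activity. The labels put all libraries in 1 batch. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 and the genome build GRCm38 (mm10), and the roles of the tools were not given in the sources used here. The deposited expected counts are RSEM expected counts per gene, not scaled to depth, which the authors deposited as whole numbers, so rounding to whole numbers before testing changed none of them. The deposited FPKM values are fragments scaled to transcript length and to mapped fragments, computed by the authors and given to 2 decimals. The strand setting and the annotation release were not given either. Of the gene identifiers of the count table, 99.4% were found in GENCODE M21.

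The count table had 55487 gene rows, and 55491 rows were in the table of FPKM. No count was recorded in any library for 15369 genes, and 114 symbols were shared by several gene identifiers, so genes were tested by identifier. Library totals ranged from 7.08 to 20.4 M with a median of 11.7 M. Replicates of a group differed by more than counting noise, with a lowest chi-square per degree of freedom of 18 over 25 pairs of replicates. The Pearson r of log2 CPM between libraries was 0.891 to 0.974, and the Spearman rho of FPKM and count within a library 0.868 to 0.887. The rows of transgenes (cre, eGFP, tdTomato, mCherry) are in the table of FPKM alone, were read there and stayed out of the gene tests.

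Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and a quasi-likelihood model was fitted with 1 mean for each of the 8 groups of genotype, sex and age, which left 16 residual degrees of freedom. The biological coefficient of variation was 31.2%. Genotype and age effects were averaged over the sexes with equal weight. The 8 comparisons were genotype at each age, the genotype by age interaction, age in each genotype, the genotype by sex interaction at each age, and sex. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and CPM on the log scale used a prior count of 2. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F.

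Gene lists, 39 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated for each list, and with fry. The directional fry test was used, which asks whether the genes of a list shift in a common direction without reference to other genes. A list with fewer than 3 tested genes was dropped (1 list). Of the lists, 13 hold markers of cell types other than tendon fibroblasts, and their mean log2 CPM was compared between genotypes by exact permutation within sex.

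Genes are named by a rule set before the data were examined. It takes the targeted gene and the AMPK subunit genes, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and a gene symbol, then up to 4 members of smallest p from each list. Where fewer than 5 genes passed in a direction, the 5 of smallest p are given as not passing. The comparisons of age in cKO, of sex and of genotype by sex used 5 per direction. Dbp was added after its values were seen. Some genes that the rule takes are not reported here. The model, filter, lists, chance splits and most alternatives were also set before the data were examined.

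Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with a pseudocount of 0.1 or 1, RLE scaling, no filter, a stricter filter (1 CPM in 6 libraries), an additive sex term, only the libraries of 1 age, the muscle marker level as a covariate, a block by replicate number, and each of the 24 libraries left out. Sample quality weights and 2 surrogate variables (sva 3.50.0) were added after the data were seen. Labels were reshuffled within the other factors in 40 splits per factor. Correlations and figures used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9, with up to 100000 resamples for permutation.

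The procedure was tested on simulated data with 100 genes changed at each fold size. The changed genes had a mean of at least 1 CPM, and the same fold was set for every library of the changed group. The recovery rates therefore do not cover genes of lower counts or groups whose libraries differ in response. By edgeR, 56% of 2-fold and 91% of 4-fold changes were recovered for genotype at 1 month (6 unchanged genes called), 49% and 86% for genotype at 3 months, 56% and 89% for age in wildtype, 54% and 96% for age in cKO, 82% and 100% for sex, 30% and 65% for genotype by age, 6% and 66% for genotype by sex at 1 month, and 2% and 45% at 3 months. For genotype at 1 month DESeq2 recovered 64% and 95% and called 28 unchanged genes, and limma-voom recovered 59% and 88% and called 6. A list of 20 genes shifted 1.4-fold was recovered by camera in all 4 comparisons simulated, with 0 of the unshifted lists called. The simulated genes were drawn independently, while genes of the real lists were correlated (estimated correlation 0.862 for oxidative phosphorylation). The simulation therefore does not show how often camera calls an unshifted list of correlated genes.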

Results

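RNA sequencing of whole mouse Achilles tendon compared wildtype mice with AMPKcKO mice (cKO), a line described by its labels as lacking AMPKα1, the catalytic subunit of the energy sensor AMP-activated protein kinase encoded by Prkaa1. The animals had cage activity and were 1 or 3 months old. The 24 libraries comprised 6 wildtype and 6 cKO libraries at 1 month, with 3 of each sex, and 5 wildtype (2 female, 3 male) and 7 cKO libraries (3 female, 4 male) at 3 months. The labels of the older libraries named no age, and 3 months was assigned by elimination because the study describes only the ages of 1 and 3 months. The labels did not say that the libraries came from separate animals, so every p-value measures only the spread between these samples, which may be technical. Total counts at 1 month were 12.5, 10.1 and 11.7 M in wildtype females, 7.08, 11.7 and 9.88 M in wildtype males, 12.98, 20.4 and 8.58 M in cKO females, and 10.3, 9.10 and 10.5 M in cKO males. At 3 months they were 10.1 and 14.6 M in wildtype females, 15.9, 12.2 and 9.45 M in wildtype males, 12.1, 14.5 and 15.4 M in cKO females, and 16.6, 7.32, 16.4 and 11.2 M in cKO males. After removal of genes with few counts, 19137 genes were tested.

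The tendons carried a variable amount of skeletal muscle transcript. Ttn, which encodes the giant sarcomere protein titin, took from 1.61% to 12.2% of all counts in a library, and Myh7, the slow myosin heavy chain, ranged from 1052 to 20781 CPM (counts scaled to library size). Col1a1, the main collagen chain of tendon, took from 0.34% to 13.2%. Xist, the RNA of the inactive X chromosome, was at 581 to 982 CPM in the 11 female libraries and at or under 0.5 CPM in the 13 male libraries. Ddx3y on the Y chromosome was at 58.8 to 88 CPM in males and at or under 0.2 CPM in females.

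Prkaa1, the targeted gene (ENSMUSG00000050697, GRCm38 chromosome 15, 5143861 to 5181899), was still counted in every cKO library. At 1 month the wildtype libraries had 18.6, 17.6 and 23.2 CPM (female) and 24, 15.4 and 22.3 CPM (male), and the cKO libraries 16.3, 17 and 17 CPM (female) and 12.3, 15.4 and 21.3 CPM (male). At 3 months the wildtype libraries had 13.5 and 27.4 CPM (female) and 28.2, 28 and 21.5 CPM (male), and the cKO libraries 16.3, 14.8 and 18.5 CPM (female) and 17.3, 19.9, 20.6 and 13.6 CPM (male). The group means were 20.2 ± 3.47 (SD, n = 6) against 16.6 ± 2.91 CPM (n = 6) at 1 month, with a two-sided exact permutation p of 0.065. At 3 months they were 23.7 ± 6.33 (n = 5) against 17.3 ± 2.58 CPM (n = 7), with an exact permutation p of 0.0886. The log2 fold changes of Prkaa1 were -0.28 ± 0.17 (SE) at 1 month (edgeR adjusted p = 0.706) and -0.43 ± 0.17 at 3 months (adjusted p = 1), so the difference did not pass at either age. A count over the whole gene includes any exons left by the deletion, and the labels did not say which part was deleted. It also includes reads from any cells of the whole tissue that kept the gene, and the labels did not name the cells targeted. These sources cannot be told apart here. A cre transcript, absent from all 11 wildtype libraries (0 FPKM), was listed at 0.51 to 5.14 FPKM in all 13 cKO libraries. Every genotype comparison is therefore also a comparison of libraries with and without cre. Of the other subunit genes at 1 month, Prkaa2, which encodes the α2 catalytic subunit, had a log2 fold change of 0.72 ± 0.43, Prkab1 0.21 ± 0.15, Prkab2 0.79 ± 0.50, Prkag1 -0.07 ± 0.12, Prkag2 0.10 ± 0.12 and Prkag3, the muscle γ3 subunit, 2.12 ± 0.99. At 3 months the same genes had -0.06 ± 0.43, 0.09 ± 0.15, 0.56 ± 0.51, 0.07 ± 0.13, -0.06 ± 0.12 and 1.07 ± 0.93. None of these 6 genes passed at either age in edgeR (lowest adjusted p = 0.634, for Prkag3 at 1 month).

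**Figure D1:**
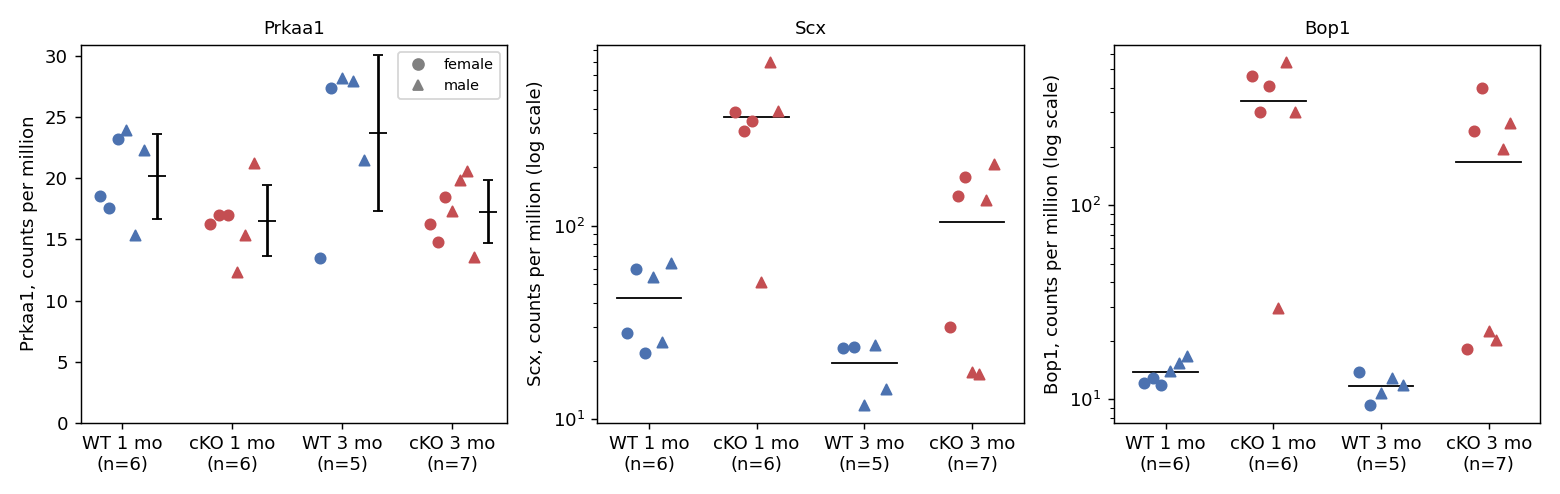
CPM of Prkaa1 (linear axis, with mean ± SD), Scx and Bop1 (log axes, horizontal line at the mean) in each library, with wildtype (WT) in blue, cKO in red, circles for females and triangles for males. Prkaa1 overlapped between genotypes, while the cKO libraries reached 699 CPM for Scx and 547 CPM for Bop1 and 4 of them lay near the wildtype libraries.

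The cKO and wildtype libraries were compared at 1 month, while the tendon grows. Arntl, the core clock activator BMAL1, was at 33.5 ± 20.9 CPM (SD, n = 6) against 5.85 ± 3.06 CPM in wildtype (n = 6), a log2 fold change of 2.64 ± 0.48 (SE). The cKO libraries were uneven, with Arntl at 48.42, 58.63 and 11.04 CPM in females and 6.29, 42.21 and 34.55 CPM in males against 2.57 to 9.88 CPM in wildtype. Thus cKO male 1 lay within the wildtype range and cKO female 3 just above it. Ccn2, a matricellular target of TGF-beta and mechanical load, was at 139 ± 67.5 against 448 ± 165 CPM (-1.75 ± 0.31). Of the genes of smallest p, the largest differences were those of Bop1, a ribosome assembly factor (343 ± 180 against 13.9 ± 1.95 CPM, 4.62 ± 0.76), and Scx, the tendon transcription factor scleraxis (363 ± 207 against 42.1 ± 19.1 CPM, 3.12 ± 0.65). Other genes with the smallest p were Dio2, which activates thyroid hormone (2.55 ± 0.51), the tubulin acetyltransferase gene Atat1 (0.83 ± 0.18), the exchange factor gene Arhgef4 (-0.99 ± 0.16), Sertad2 (-0.64 ± 0.12), the transcription factor gene Cebpd (-1.12 ± 0.21) and the spermidine synthase gene Srm (-1.06 ± 0.21).

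None of these genes passed the adjustment over all genes. The edgeR quasi-likelihood test called 0 higher and 0 lower, with a lowest adjusted p of 0.0628 for Arhgef4, against 0.0727 for Bop1, 0.0818 for Ccn2, 0.0837 for Arntl, Sertad2 and Cebpd, 0.115 for Srm, 0.128 for Dio2, 0.181 for Scx and 0.201 for Atat1. There were 1471 genes at an unadjusted p under 0.05, where 957 would be expected by chance. DESeq2 called 23 higher and 54 lower, limma-voom 0 and 2, and limma on log2 FPKM 0. The count rested on single libraries, since leaving out cKO male 1 gave 57 calls, cKO female 3 gave 16, wildtype male 2 gave 3, and the 3-month libraries cKO female 4, cKO male 3 and wildtype male 4 gave 3, 2 and 1.

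Scx and Bop1 occupy the same locus. Scx (GRCm38 chromosome 15, 76457452 to 76459458, plus strand, 2 exons) lies inside intron 3 of Bop1 (76456027 to 76466771), on the opposite strand of Bop1 (76452989 to 76477277), and whether the counting used strand was not given in the sources used here. Reads of the 2 genes may be shared, and both values are uncertain. The exact permutation p within sex was 0.015 for Scx and 0.005 for Bop1 at 1 month (n = 6 and 6), and 0.0257 and 0.0171 at 3 months (n = 5 and 7). An eGFP transcript was at 0 FPKM in all 11 wildtype libraries, at 287 to 1256 FPKM in 9 cKO libraries and at 1.4 to 11.8 FPKM in the other 4 cKO libraries. Those 4 were cKO male 1 at 1 month, and cKO female 4, male 3 and male 5 at 3 months. The mix of high and low eGFP among cKO libraries thus differed between ages. Omission of cKO male 1 (11.8 FPKM) gave 57 calls at 1 month, and omission of cKO female 3 (897.93 FPKM) gave 16. In 3 of the 4 libraries with little eGFP, Scx lay within the wildtype range of its age. Bop1 lay above that range in all 4 (29.6, 18.2, 20.2 and 22.4 CPM).

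Among the 39 gene lists, the circadian clock list was the only list that fry called at 1 month. By camera, skeletal muscle had the lowest adjusted p. All 19 clock genes were measured, and by edgeR 0 passed over all genes while 18 passed when adjusted over the list alone. Arntl and Clock (0.54 ± 0.13), which activate the loop, were higher in cKO, and the repressors Per1 (-1.78 ± 0.42) and Nr1d1 (-0.94 ± 0.23) were lower. Dbp, a clock output gene chosen after its values were seen, was at 43.1 ± 48.9 against 147 ± 57 CPM (n = 6 and 6; exact permutation p = 0.02). In cKO male 1 and cKO female 3 Dbp was at 109.05 and 103.25 CPM, within the wildtype range. The camera test placed the list below other genes (adjusted p = 1.23e-06; adjusted p = 0.433 with an estimated correlation), and fry gave an adjusted p of 0.0439. DESeq2 called 3 of the 19 genes higher and 3 lower.

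**Figure D2:**
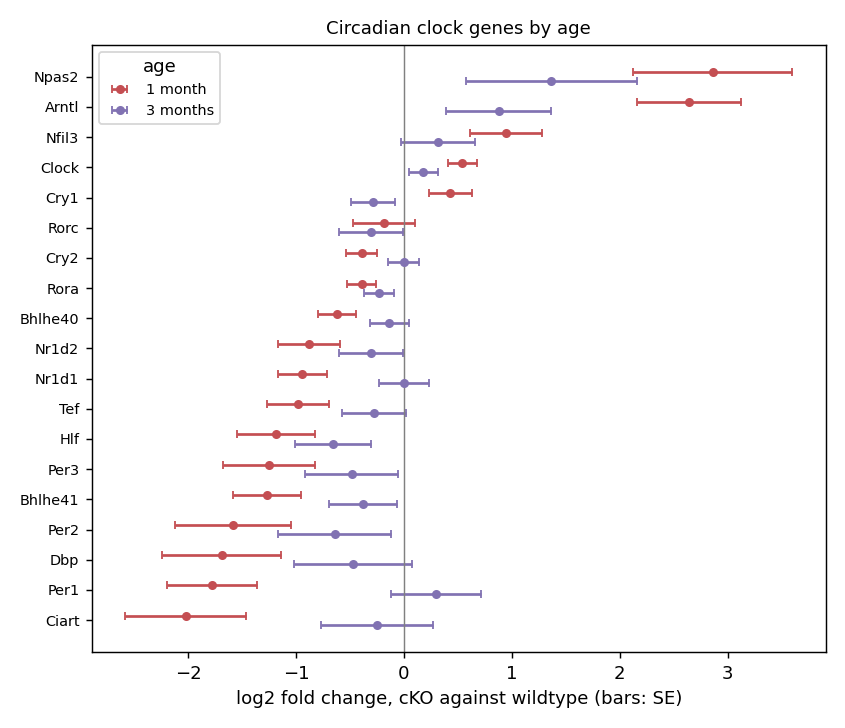
Log2 fold change of 19 circadian clock genes, cKO against wildtype, at 1 month (red) and 3 months (purple), as point estimate with bars of 1 SE. At 1 month Arntl stood at 2.64 and Per1 at -1.78, against 0.88 and 0.30 at 3 months, and by edgeR none passed over all genes at either age. DESeq2 called 3 of the 19 higher and 3 lower at 1 month.

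Muscle and mitochondrial genes mostly had positive fold changes at 1 month. None of these genes passed over all genes by edgeR. All 22 skeletal muscle markers had positive log2 fold changes (median 1.06; Tnnc2 1.19 ± 0.48, Tnnt3 1.36 ± 0.56), and the mean level of the list was 9.998 ± 0.927 (SD, n = 6) against 8.82 ± 1.22 log2 CPM (n = 6), a difference that did not pass (exact permutation p = 0.065, adjusted p = 0.748). Of 31 nuclear genes of oxidative phosphorylation, 29 were positive (median 0.33; Cycs 0.61 ± 0.30, Ndufs7 0.47 ± 0.28), as were all 13 mitochondrially encoded genes (median 0.32), 17 of 20 fatty acid oxidation genes (median 0.31), 14 of 18 glycolysis genes (0.33) and 16 of 20 genes of mitochondrial biogenesis (0.17). Cpt1a, the entry enzyme of mitochondrial fatty acid import, went the other way (-0.74 ± 0.21) and was the 1 fatty acid oxidation gene that passed when adjusted over the list alone. By camera, the muscle list was called higher (adjusted p = 3.88e-08), with oxidative phosphorylation (1.07e-05), the mitochondrially encoded genes (0.0132), fatty acid oxidation (0.0287), glycolysis (0.0353), biogenesis (0.0353), proliferation (0.028), pericytes (0.028) and endothelial cells (0.0355). Each of these 9 lists had an adjusted p = 0.765 with an estimated correlation. With the muscle level as a covariate, the median of the oxidative phosphorylation genes was -0.01 and its adjusted p 0.931, and glycolysis (0.437), mitochondrially encoded genes (0.525), biogenesis (0.309) and fatty acid oxidation (0.819) turned direction without passing.

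Matrix genes mostly had negative fold changes at 1 month, and 0 of them passed over all genes by edgeR. Of 22 genes of collagen processing, 19 were negative (median -0.31; camera adjusted p = 0.00293; adjusted p = 0.765 with an estimated correlation), among them the lysyl hydroxylase gene Plod1 (-0.48 ± 0.13), the prolyl hydroxylase gene P4ha1 (-0.58 ± 0.23) and the collagen chaperone gene Fkbp10 (-0.60 ± 0.22). Of 24 genes of TGF-beta signalling and mechanoresponse, 17 were negative (median -0.24, adjusted p = 0.0144; adjusted p = 0.765 with an estimated correlation) and 4 passed when adjusted over the list alone, with Ccn2, Id1 (-0.76 ± 0.20) and Ccn1 (-0.84 ± 0.28) among those of smallest p. The proteoglycan and elastic fibre list (median -0.21, adjusted p = 0.0353), all 24 ribosomal protein genes (median -0.20, adjusted p = 1.47e-05; Rpl18 -0.31 ± 0.11) and the 12 skin keratinocyte markers (median -2.985, adjusted p = 0.00293; Krt10 -3.30 ± 1.01) completed the 6 lists called lower. Each of these other than the clock list had an adjusted p = 0.765 with an estimated correlation, and the muscle level was the higher in cKO in the same libraries. The skin list rested on wildtype male 3, whose level was 5.51 log2 CPM against -1.08 to -0.571 in the other 5 wildtype libraries. By edgeR no gene of any list passed over all genes, while 36 passed when adjusted over their list alone. DESeq2 called 3 clock genes higher and 3 lower, and 1 tendon fibroblast marker higher. The 17 collagens (median -0.27, camera adjusted p = 0.0761) and 20 tendon fibroblast markers (median -0.29, adjusted p = 0.092) did not pass. With the muscle covariate, the calls of collagen processing (adjusted p = 0.555), the TGF-beta list (0.525), ribosomal proteins (0.0849) and the proteoglycan list (0.0778, in the opposite direction) ended. So did those of skin (0.0863), pericytes (0.0555) and endothelial cells (0.897), while the clock (2.3e-07) and proliferation (0.00348) kept theirs. Only the muscle, oxidative phosphorylation, clock and ribosomal calls held whichever library was left out. The other 11 of the 15 each ended without some single library. Without wildtype male 3 the adjusted p was 0.719 for skin, 0.34 for biogenesis, 0.294 for mitochondrially encoded genes, 0.258 for proteoglycans and 0.0692 for collagen processing. Without cKO male 3 it was 0.41 for endothelial cells, 0.399 for fatty acid oxidation and 0.111 for glycolysis. Proliferation turned direction without wildtype male 2 (0.9), pericytes ended without wildtype male 1 (0.131) and the TGF-beta list without wildtype female 2 (0.071).

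At 3 months most tendon fibroblast markers and mitochondrial genes had small negative fold changes in cKO and most immediate early genes positive values. None of these genes passed over all genes by edgeR. Of the 20 immediate early genes, which respond within minutes to stimulation, 18 were positive (median 0.34; Nr4a2 0.56 ± 0.26, Nr4a1 0.69 ± 0.36, Fosb 0.55 ± 0.30, Klf4 0.38 ± 0.21). Of 20 tendon fibroblast markers, 17 were negative (median -0.36), including the tendon transcription factor Mkx (-0.49 ± 0.26) and Fibin (-0.58 ± 0.31). The 17 collagens were even (9 positive, 8 negative, median 0.016, camera adjusted p = 0.793), and of the 22 collagen processing genes 16 were negative (median -0.029, adjusted p = 0.793). All 31 nuclear oxidative phosphorylation genes (median -0.18; Cox6c -0.44 ± 0.29) and all 13 mitochondrially encoded genes (median -0.29; mt-Nd3 -0.43 ± 0.28) were negative, while the muscle list level was the same within its spread (10.3 ± 1.18, n = 7, against 10.3 ± 1.09 log2 CPM, n = 5; exact permutation p = 0.963). The 9 mast cell markers were positive (median 0.78; Hdc, the histamine-forming enzyme, 0.99 ± 0.39), and the 6 red blood cell genes negative (median -0.93; Alas2 -0.94 ± 0.43, Hba-a2 -1.32 ± 0.63). The levels per library of the mast cell list (exact permutation p = 0.297) and the red blood cell list (p = 0.171) did not pass (adjusted p = 0.963 for each), and cKO male 5 had a red blood cell level of 3.97 log2 CPM against 0.752 to 2.02 in the other cKO libraries.

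By camera, 3 lists were called higher at 3 months, namely immediate early genes (adjusted p = 5.25e-07; adjusted p = 0.406 with an estimated correlation), mast cells (0.00459) and adipocytes (0.0306). The 6 called lower were tendon markers (0.000596), red blood cells (0.000596), oxidative phosphorylation (0.00869), mitochondrially encoded genes (0.0262), the proteoglycan list (0.0262; Comp -0.56 ± 0.34) and fatty acid and sterol synthesis (0.0494). Each of the 8 lists other than immediate early genes had an adjusted p = 0.962 with an estimated correlation, and fry called 0 lists. Over all genes, edgeR called 0 genes higher and 0 lower with 424 at an unadjusted p under 0.05, DESeq2 called 1 higher and 0 lower, and limma-voom and limma on log2 FPKM called 0. The genes of smallest p had values of 3.84 ± 0.82 (Bop1), 2.40 ± 0.69 (Scx), 0.60 ± 0.17 (Fam122a), 0.33 ± 0.10 (Smad1) and 0.78 ± 0.24 (Has2, a hyaluronan synthase gene) on the higher side. On the lower side they were -1.14 ± 0.29 (Epha5), -2.17 ± 0.55 (Kpna2-ps), -0.37 ± 0.12 (Mfhas1), -1.13 ± 0.36 (Stk32a) and -0.45 ± 0.15 (Rbis), all with an adjusted p of 1. Across all 19137 genes the fold changes at 1 and 3 months were nearly unrelated (Pearson r = 0.08 across genes, which are not independent replicates). Without wildtype female 5 at 3 months the camera calls at that age numbered 5 and the proteoglycan list turned direction (adjusted p = 0.799). Without wildtype male 4 they numbered 3. Of the 9 lists, only immediate early genes kept the call whichever library was left out (highest adjusted p = 0.0393). The fatty acid and sterol synthesis call ended with the muscle covariate (0.0588).

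**Figure D3:**
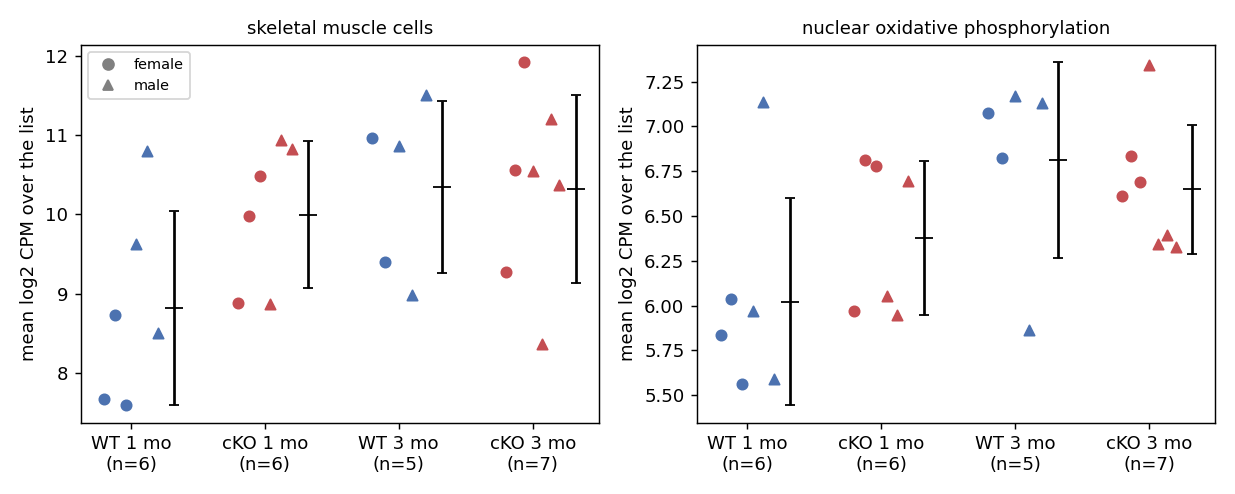
Mean log2 CPM per library of 22 skeletal muscle markers and 31 nuclear oxidative phosphorylation genes in wildtype (WT, blue) and cKO (red) at 1 and 3 months, circles for females and triangles for males, black bars for mean ± SD. At 1 month the muscle level averaged 8.82 in wildtype and 9.998 in cKO, and at 3 months 10.3 in both.

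The genotype by age interaction asked whether the cKO difference itself changed between ages. The mix of cKO libraries with high and low eGFP also differed between the ages. Cebpd (1.29 ± 0.30), Zfp358 (0.99 ± 0.23), Mnt (0.62 ± 0.15), Arhgef4 (0.95 ± 0.23) and Trp53inp1 (0.74 ± 0.18) had the smallest p on the positive side, and Cd274 (-1.37 ± 0.35), Plxna4os2 (-1.83 ± 0.49), Pnpla3 (-1.49 ± 0.41), Cyb5b (-0.68 ± 0.19) and Emx2os (-1.76 ± 0.52) on the negative side. The interaction was -1.76 ± 0.66 for Arntl, 2.08 ± 0.59 for Per1, 1.52 ± 0.43 for Ccn2, 1.46 ± 0.42 for Fosb, -0.95 ± 0.43 for Cycs and -0.14 ± 0.24 for Prkaa1. All had an adjusted p of 1. By edgeR 0 genes passed in either direction, with 721 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 0 lower while limma-voom and limma on log2 FPKM called 0. Leaving out cKO female 3 at 1 month gave 1 call. By camera 5 lists had a positive and 7 a negative interaction, led by nuclear oxidative phosphorylation (median -0.54, adjusted p = 5.04e-08; adjusted p = 0.79 with an estimated correlation) and immediate early genes (19 of 20 positive, adjusted p = 7.22e-06; adjusted p = 0.574 with an estimated correlation), and 0 held with an estimated correlation. The 22 muscle markers were all negative in this interaction (median -0.84) beside the mitochondrial genes.

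Between 1 and 3 months in wildtype, the genes that build the collagen matrix fell. Of 17 tendon collagens, 14 fell and 0 rose (median log2 fold change -1.58), and all 17 passed when adjusted over the list alone. Col1a1 (ENSMUSG00000001506, GRCm38 chromosome 11, 94936224 to 94953042) went from 105000 ± 33200 CPM (SD, n = 6) to 10500 ± 4580 CPM (n = 5), a log2 fold change of -3.30 ± 0.50 (SE, edgeR adjusted p = 0.000462) that is 9.82-fold lower. Col1a2 fell by 2.87 ± 0.44, Col11a1 by 2.29 ± 0.34 and Col15a1 by 1.80 ± 0.27 on the log2 scale. Of 22 genes of collagen processing, 18 fell, 0 rose and 4 did not pass (19 when adjusted over the list alone), among them the lysyl oxidase-like gene Loxl2 (fell by 2.91 ± 0.35), Plod1 (1.41 ± 0.15), Fkbp10 (1.83 ± 0.24) and P4ha1 (1.91 ± 0.26). Tnmd, the tendon marker tenomodulin, fell by 2.37 ± 0.32 and Cilp2 by 1.44 ± 0.32, 2 of the 9 of 20 tendon markers that fell (13 over the list alone). On log2(FPKM + 0.1), 11 collagens, 11 processing genes and 5 tendon markers fell. With the muscle level as a covariate, 13 collagens, 13 processing genes and 6 tendon markers fell. Their medians were then -1.352, -1.057 and -0.668, against -1.583, -1.364 and -1.076 without it. With 2 surrogate variables, an alternative chosen after seeing the data, 9 collagens fell and their median was -0.951.

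**Figure D4:**
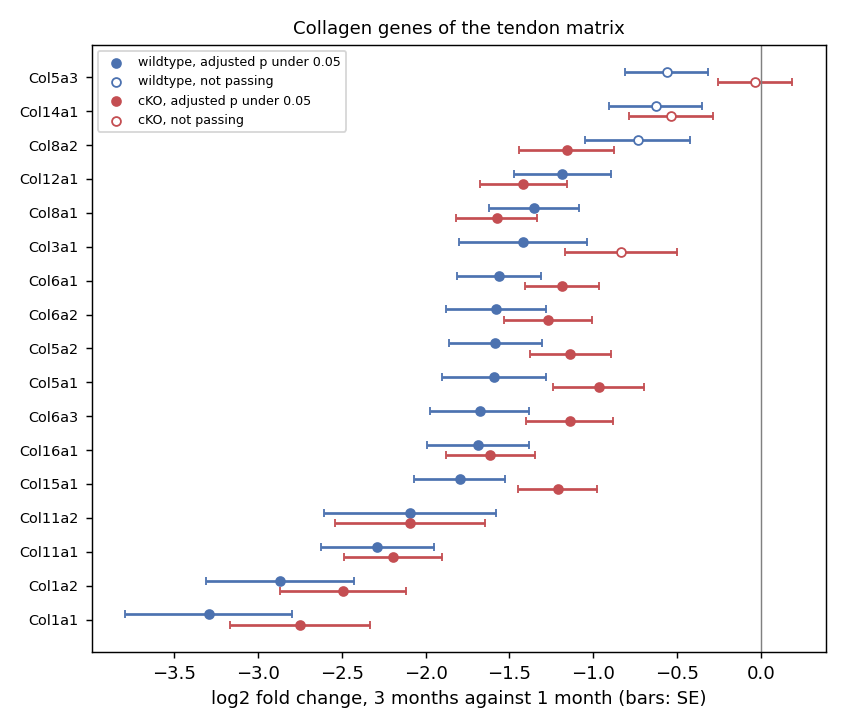
Log2 fold change from 1 to 3 months of 17 tendon collagen genes in wildtype (blue) and cKO (red), with bars of 1 SE and filled points where the edgeR adjusted p was under 0.05. In each genotype 14 of the 17 fell, with Col1a1 at -3.30 in wildtype and -2.75 in cKO.

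Most imprinted growth genes and a minority of the genes in several other lists fell over the same interval in wildtype. Of 12 imprinted growth genes, 7 fell and 0 rose, including the growth factor gene Igf2 (95.5 ± 12.3 to 25.9 ± 12 CPM, fell by 1.86 ± 0.23), the non-coding RNA Meg3 (2.47 ± 0.27), Plagl1 (1.32 ± 0.21) and Peg3 (0.99 ± 0.18). This list alone kept its call with an estimated correlation (camera adjusted p = 3.54e-07; adjusted p = 0.0343 with an estimated correlation; fry adjusted p = 2.51e-06). Of 16 IGF axis genes 4 fell, among them Igf1r (0.58 ± 0.11), Igfbp2 (2.89 ± 0.63) and Igfbp4 (1.09 ± 0.26). Of 33 proteoglycan, elastic fibre and matricellular genes 15 fell (16 over the list alone), such as Matn2 (2.14 ± 0.27), the fibrillin gene Fbn2 (2.62 ± 0.43) and elastin, Eln (1.38 ± 0.26). Of 22 cartilage and ossification genes 5 fell (6 over the list alone), led by the aggrecan gene Acan (3.53 ± 0.60), Col2a1 (3.48 ± 0.72), Hapln1 (2.23 ± 0.51) and Col9a2 (2.97 ± 0.72). Of 24 TGF-beta and mechanoresponse genes 6 fell and 1 rose (11 over the list alone), with Ltbp1 (0.85 ± 0.19), the mechanosensitive channel gene Piezo1 (0.78 ± 0.18) and Tgfbi (1.17 ± 0.31) among those that fell. Of 20 matrix proteases and inhibitors 5 fell, including Mmp23 (1.65 ± 0.27), Ctsk (log2 fold change -1.505 ± 0.328) and Timp1 (1.73 ± 0.43). This list was not called (camera adjusted p = 0.0532). Asns, a target of the integrated stress response, fell by 1.61 ± 0.23 and Herpud1 by 0.65 ± 0.16, the 2 of 21 stress response genes that passed (list adjusted p = 0.0474; adjusted p = 0.48 with an estimated correlation).

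A minority of mitochondrial genes rose with age in wildtype, beside positive values of the muscle markers. Of 31 nuclear oxidative phosphorylation genes, all positive (median 0.82), 5 rose and 23 passed when adjusted over the list alone, including Cox6c (1.17 ± 0.30), Cox5b (0.99 ± 0.26), Cycs (1.20 ± 0.32) and Ndufs7 (1.02 ± 0.29). Of the 13 mitochondrially encoded genes 2 rose, namely mt-Nd2 (1.32 ± 0.40) and mt-Nd3 (0.95 ± 0.29), and 13 passed over the list alone. Of 20 fatty acid oxidation genes 4 rose and 1 fell (15 over the list alone), with Acads (0.73 ± 0.18), Fabp3 (1.68 ± 0.48) and Acadm (1.02 ± 0.29) rising and Cpt1a falling by 0.76 ± 0.22. All 22 muscle markers were positive (median 1.46), of which Tnnc2 alone passed over all genes (1.75 ± 0.50), and the mean muscle level was 8.82 ± 1.22 log2 CPM (n = 6) at 1 month and 10.3 ± 1.09 (n = 5) at 3 months. With the muscle level as a covariate, 0 of the 31 nuclear oxidative phosphorylation genes rose (median 0.34) although the list kept its call (camera adjusted p = 0.000716; without the covariate adjusted p = 0.427 with an estimated correlation). With 2 surrogate variables their median was -0.05. The antioxidant gene Nqo1 rose by 1.58 ± 0.25 and Prdx3 by 1.09 ± 0.23, 2 of the 4 of 22 antioxidant genes that rose. The interferon-inducible genes Gbp2 (1.303 ± 0.28) and Iigp1 (1.26 ± 0.35) also rose, 2 of the 3 of 22 that rose in that list.

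The 10 largest rises in wildtype were those of Pon1 (log2 fold change 4.30 ± 0.67), Hs3st5 (3.94 ± 0.81), Mettl11b (3.76 ± 0.97), Mylk4 (3.27 ± 0.88), Snhg11 (2.98 ± 0.48), Gbp10 (2.89 ± 0.82), the ketone body enzyme gene Bdh1 (2.83 ± 0.62), Dupd1 (2.76 ± 0.68), Myh15 (2.696 ± 0.60) and Nos1 (2.57 ± 0.67). The 10 largest falls were those of Glp1r (-6.16 ± 0.77), the angiotensin receptor gene Agtr2 (-4.15 ± 0.73), the BMP antagonist gene Grem1 (-3.88 ± 0.72), the cystine transporter gene Slc7a11 (-3.84 ± 0.53), Acan, Col2a1, Col1a1, Cpz (-3.29 ± 0.44), Nell2 (-3.08 ± 0.51) and Cthrc1 (-3.03 ± 0.59). In all, edgeR called 578 genes higher and 1079 lower at 3 months, with 4803 at an unadjusted p under 0.05. DESeq2 called 1140 higher and 1345 lower, and limma on log2(FPKM + 0.1) called 344 and 234, which turned the balance of directions. The count fell to 566 without wildtype female 4 at 3 months and rose to 2852 without wildtype male 2 at 1 month, the 1-month wildtype library with the most Ttn.

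By camera 18 lists were called in wildtype, 8 higher and 10 lower, and fry called 9. Apart from the imprinted growth genes (3.54e-07), the lowest camera adjusted p values were those of collagen processing (8.11e-19; adjusted p = 0.165 with an estimated correlation), collagens (1.35e-17; adjusted p = 0.165 with an estimated correlation), oxidative phosphorylation (4.91e-11), tendon markers (7.21e-09), proteoglycans (3.11e-08), fatty acid oxidation (5.82e-07), mitochondrially encoded genes (1.5e-06) and muscle (1.5e-06). The latter 6, with adipocytes (0.000252), mitochondrial biogenesis (0.000636), inflammation (0.00674), cartilage (0.0147), pericytes (0.0161) and the IGF axis (0.0213), had an adjusted p = 0.427 with an estimated correlation. The TGF-beta (0.0163) and stress response (0.0474) lists had an adjusted p = 0.48 with an estimated correlation, and ribosomal proteins (0.0218) had an adjusted p = 0.763 with an estimated correlation. The muscle markers were positive in the same libraries, and with the muscle level as a covariate 6 of the 18 calls ended. The muscle list itself, 1 of the 18, was not tested with that covariate. These were mitochondrial biogenesis (adjusted p = 0.369), cartilage (0.196), the stress response (0.201), TGF-beta (0.347), the IGF axis (0.113) and ribosomal proteins (0.861). With single libraries left out 14 calls held, and those of inflammation (0.0504), TGF-beta (0.0538), the stress response (0.156) and ribosomal proteins (0.217) ended.

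The same interval in cKO tendons gave 319 genes higher and 867 lower by edgeR, with 3691 at an unadjusted p under 0.05. The cKO libraries of the ages compared also differed in their mix of high and low eGFP. Of 17 collagens 14 fell (median -1.21), of 22 processing genes 15 fell (median -1.06), of 20 tendon markers 10 fell (median -1.20) and of 12 imprinted growth genes 5 fell (16, 19, 14 and 6 when adjusted over each list alone). On log2(FPKM + 0.1) these counts were 6, 4, 4 and 3, with medians of -1.119, -0.941, -1.15 and -0.474. Of 15 adipocyte genes 5 rose and of 19 clock genes 3 rose, while 0 of 31 nuclear oxidative phosphorylation genes passed. By camera 9 lists were higher and 7 lower, among them collagen processing (1.61e-19; adjusted p = 0.123 with an estimated correlation), collagens (2.17e-19; adjusted p = 0.123 with an estimated correlation) and adipocytes (1.9e-09; adjusted p = 0.347 with an estimated correlation), and the imprinted growth genes alone kept their call (1.82e-07; adjusted p = 0.0285 with an estimated correlation). The largest rises were those of Rasd2 (3.66 ± 0.90), Gbp10 (3.47 ± 0.84), Mycl (2.51 ± 0.57), Stk32b (2.24 ± 0.53) and the MHC class II gene H2-Aa (2.21 ± 0.47), and the largest falls those of Igfbp2 (-4.06 ± 0.62), Scrg1 (-3.80 ± 0.68), Slc7a11 (-3.47 ± 0.44), Grem1 (-3.41 ± 0.65) and Nell2 (-3.40 ± 0.46). Both genotypes shared 101 genes that rose and 572 that fell, where 9.6 and 48.9 would be expected from independent lists, and 0 went in opposite directions. Of the 1657 genes called in wildtype, 97.8% had the same sign in cKO. The fold changes of the 2 genotypes correlated at r = 0.588 across genes, which are not independent replicates. DESeq2 called 618 higher and 1036 lower, limma on log2(FPKM + 0.1) 97 and 123, and omission of cKO female 1 at 1 month left 646 genes.

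Sex was compared over both genotypes and ages. Males had more of the Y-linked transcripts Ddx3y (11.43 ± 0.21), Eif2s3y (11.36 ± 0.21), Kdm5d (9.36 ± 0.22) and Uty (9.01 ± 0.28) and of the complement gene C7 (3.90 ± 0.35, edgeR adjusted p = 2.42e-06). Females had more Xist (-12.47 ± 0.32), Kdm6a, which escapes X inactivation (-0.92 ± 0.07), Ano4 (-2.11 ± 0.36) and Igfbp3 (-1.31 ± 0.22). edgeR called 23 genes higher in males and 17 higher in females, with 1604 at an unadjusted p under 0.05, DESeq2 84 and 79, and limma-voom 21 and 16. The count was 64 without wildtype male 2 at 1 month.

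Whether the cKO difference depended on sex was tested at each age. At 1 month the genes of smallest p were Cebpd (2.32 ± 0.42), Trp53inp1 (1.402 ± 0.253), the ubiquitin ligase gene Nedd4l (1.15 ± 0.22), Grik5 (1.59 ± 0.34) and Ip6k1 (0.91 ± 0.20), where the cKO difference was the more positive in males, and Stmn2 (-2.33 ± 0.42), Cetn3 (-1.46 ± 0.28), Gbp10 (-9.50 ± 1.96), Baz1a (-1.59 ± 0.34) and Gvin1 (-2.49 ± 0.53). The lowest edgeR adjusted p was 0.115, so 0 genes passed in either direction, with 1921 at an unadjusted p under 0.05, while DESeq2 called 14 and 22, limma-voom 0 and limma on log2 FPKM 0. Scaling by log2(FPKM + 0.1) moved the median of all genes by 0.163 here and by 0.111 at 3 months. Leaving out cKO male 2 gave 1 call. At 3 months the smallest p were those of Snrpd2 (0.69 ± 0.22), Bad (0.77 ± 0.25), Ccm2 (0.88 ± 0.29), Oser1 (0.80 ± 0.28), Rpl28 (0.65 ± 0.24), Fosb (-1.98 ± 0.61), B3galt4 (-1.76 ± 0.56), Krt15 (-12.35 ± 3.95), Zfp942 (-0.69 ± 0.23) and Mamstr (-1.32 ± 0.47), all with an adjusted p of 1. Here edgeR called 0 genes with 252 at an unadjusted p under 0.05, and DESeq2, limma-voom and limma on log2 FPKM called 0.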

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

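The search for libraries far from their group and for lists whose genotype effect differed between ages was set before the data were examined. Of 120 tests, each of 1 measure in 1 group, 11 flagged a far library. About 6 would be flagged by chance, since each test has a chance of about 1 in 20. The tests were not independent, since measures of a library are related and the 3-month cKO males were tested alone and within all 3-month cKO libraries. The value given is the gap to the nearest library over the range of the group. At 1 month these were wildtype male 2 with a low macrophage level (0.675), wildtype male 1 with a high T, B and NK cell level (0.85, from 3 genes), wildtype male 3 with a high skin level (0.923), cKO female 2 with the largest total (0.627) and cKO male 2 with a low adipocyte level (0.777). At 3 months wildtype female 4 had more Arntl (0.759, 12.1 against 4.04 to 5.98 CPM). The cKO male 5 stood apart for red blood cell genes (0.606 over all cKO, 0.887 within males), low Igf2 (0.58 and 0.89) and low endothelial markers (0.867). It was also the cKO library with the smallest total (7.32 M) and 1 of the 4 with little eGFP.

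By camera the genotype effect differed between ages for 12 lists, and 0 held with an estimated correlation (smallest adjusted p 0.574). They were nuclear oxidative phosphorylation (5.04e-08), mitochondrially encoded genes (0.000218), fatty acid oxidation (0.0267), fatty acid and sterol synthesis (0.0289), collagen processing (0.0264), the clock (0.000866), immediate early genes (7.22e-06), ribosomal proteins (0.00238), skeletal muscle (8e-06), pericytes (0.0264), red blood cells (0.00025) and skin (0.0164). The mean muscle level was higher in cKO by 1.174 log2 units at 1 month and by 0.035 at 3 months. The mitochondrial lists were positive beside it at 1 month, but at 3 months they were negative and kept their calls with the muscle covariate (adjusted p = 0.00103 for the nuclear and 0.00294 for the mitochondrially encoded genes). With an estimated correlation and no covariate both had an adjusted p of 0.962 at 3 months. Transgene rows were not part of the gene tests; cre reached 5.14 FPKM and eGFP 1255.58 FPKM in cKO libraries and both were 0 in wildtype.

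The tests of the Scx, clock and collagen patterns that follow were chosen after the results were seen. Scx and Bop1 counts may come in part from a reporter transgene carrying Scx sequence, since eGFP was found only in cKO libraries. Over the 9 cKO libraries above 200 FPKM, log2 Scx and log2 eGFP, as deviations from age means, correlated at r = 0.685 (exact permutation p within age 0.0236, adjusted p = 0.063; rho = 0.383, p = 0.319), but at -0.015 without the 2 farthest libraries, and Bop1 at r = 0.242 (p = 0.561). Ages were not pooled because age moves both transcripts. In the 4 cKO libraries with little eGFP, all with cre, Scx was at 51, 30.1, 17.1 and 17.6 CPM, of which 3 lay within the wildtype range of their age, so Scx was not raised in every cKO library, while Bop1 lay above that range in all 4. With log2 eGFP as a covariate the Scx difference at 1 month was -1.234 ± 0.482 against 2.903 ± 0.725 without it, and on the linear scale -61.4 ± 32.5 against 321 ± 72.6 CPM. The 9 libraries above 200 FPKM had Scx at 135 to 699 CPM and Bop1 at 194 to 547 CPM, above all 4 with little eGFP. Prkaa1 was at 13.6 to 21.3 CPM in the 9 and at 12.3 to 19.9 CPM in the 4. These values argue against a rise of this size in every cKO library. The bounds were settled after the values were seen, and eGFP exists only in cKO and may itself follow the Scx promoter. A reporter and an effect of AMPKα1 loss limited to the libraries with eGFP therefore cannot be told apart, since whole-gene Prkaa1 counts may not show the deletion. An effect of carrying cre cannot be separated either, since cre was found in every cKO library and in no wildtype library.

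The clock difference at 1 month could reflect the time of day of collection, which was not given. Arntl and Dbp deviations correlated at r = -0.751 over the 11 wildtype libraries (permutation p = 0.407, adjusted p = 0.543; rho = -0.636; r = -0.083 without the 2 farthest) and at r = -0.908 over the 13 cKO libraries (p = 0.00082, adjusted p = 0.00656; rho = -0.863; r = -0.93 without the 2 farthest), among 8 relations computed. The wildtype value rested on the 2 wildtype females of 3 months, with Arntl at 12.12 and 4.04 CPM and Dbp at 82.01 and 179.96 CPM. Exchange within such a pair only turns the sign, so the two-sided permutation could hardly give a small p there. Arntl at 3 months had a log2 fold change of 0.877 and an interaction of -1.76 ± 0.66 (adjusted p = 1), so neither time of day nor a clock effect of AMPKα1 loss at both ages was excluded. The median size of the clock fold changes was 1.046 with the muscle level as a linear covariate and 0.982 without, so a linear effect of that level did not account for them. A muscle effect of another form was not tested.

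Of the 14 collagen genes that fell in wildtype, 13 stayed called with the muscle covariate, so a linear effect of the muscle level did not account for the fall. After removal of the 20 most abundant genes the median of the collagens left was -1.581. TMM was computed again there and already trims extreme genes, so this value says little about scaling. On log2(FPKM + 0.1), which was not scaled by TMM, the collagen median was -1.51 and 11 fell. The other 18 tendon markers had a median of -1.029, with single genes from -2.37 to 0.24, so a smaller share of tendon cells and lower expression per cell cannot be told apart.

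Labels were reshuffled in 40 splits per factor, as set before the data were examined, and the count of splits at least as large as the real labels is given. For genotype at 1 month 40 splits reached the real 0 genes (highest other 120), 7 the 1471 genes at p under 0.05 (3674) and 22 the 15 lists (20). At 3 months the figures were 40 for 0 genes (0), 23 for 424 (3985) and 26 for 9 lists (19). For genotype by age they were 40 for 0 (0) and 23 for 721 (2571), for genotype by sex at 1 month 40 for 0 (16) and 4 for 1921 (3659), and at 3 months 40 for 0 (1) and 37 for 252 (3541). For age in wildtype 2 splits reached 1657 (3010), 2 reached 4803 (5773) and 12 reached 18 lists (23). For age in cKO only 1 split, the real labels, reached 1186 (635) and 3691 (3338). For sex 1 split, the real labels, reached 40 genes (3), and 11 reached the 1604 at p under 0.05 (4766). With 40 splits that include the real labels, 1 is the smallest count possible, so chance was not excluded. The sex genes include Xist and Y-linked genes, which mark the sex of a library, so reshuffled labels were bound to call fewer of them. Some splits called several times the real count. The median of the other splits was 944 genes at p under 0.05 for genotype at 1 month and 466 at 3 months. The cause of this spread between splits was not tested.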

How the results depend on the processing

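For genotype at 1 month, where edgeR called 0 genes, the count was 77 with DESeq2, 4 without a filter, 2 with limma-voom, 1 with an additive sex term and 1 with only the libraries of that age. Among alternatives chosen after seeing the data it was 260 with sample quality weights and 9 with 2 surrogate variables. Left-out libraries gave 0 to 57 calls: 57 without cKO male 1, 16 without cKO female 3, 3 without wildtype male 2, and 3, 2 and 1 without the 3-month libraries cKO female 4, cKO male 3 and wildtype male 4. DESeq2 gave 1 for genotype at 3 months (left-out libraries 0) and 1 for genotype by age (0 to 1; 1 without cKO female 3 at 1 month). For genotype by sex at 1 month it gave 36, no filter 2, quality weights 5 and surrogate variables 1 (left-out libraries 0 to 1; 1 without cKO male 2), and at 3 months left-out libraries gave 0. Prkaa1 ranged over -0.405 to -0.173 at 1 month and -0.633 to -0.122 at 3 months with libraries left out.

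For age in wildtype, against 1657 calls, the count was 1101 without a filter, 578 and 576 on log2 FPKM (pseudocount 0.1 and 1), 3236 with quality weights and 979 with surrogate variables. Left-out libraries gave 566 to 2852: 566 without the 3-month wildtype female 4, 2852 without wildtype male 2, 843 without wildtype female 2, 927 without wildtype male 1 and 867 without wildtype male 3 of 1 month, and 962 and 928 without wildtype males 4 and 6 of 3 months. For age in cKO, against 1186, it was 220 and 250 on log2 FPKM, 1792 with the muscle covariate and 2507 with quality weights (left-out libraries 646 to 1344; 646 without cKO female 1 and 748 without cKO male 2 of 1 month, 751 without cKO female 5 of 3 months). For sex, against 40, it was 163 with DESeq2, 12 and 15 on log2 FPKM, 91 with the muscle covariate, 132 with quality weights and 178 with surrogate variables (27 to 64; 64 without wildtype male 2 of 1 month). The cause of these shifts was not tested.

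Replicate numbers do not pair the genotypes: deviations of same-number libraries correlated at -0.335 to 0.41 (mean -0.03 over 10 pairs, 1 over 0.1), against a mean of 0.012 over 26 other pairs. A block by number gave 519, 73 and 6 genes for age in wildtype, age in cKO and sex, which is no measure of a smaller effect.

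Of 15 lists called at 1 month, 0 held with an estimated correlation, 1 with fry and 2 with the muscle covariate, the clock and proliferation, where 7 lists in all were called (without the covariate 8 to 17 with libraries left out; 9 without wildtype female 2, 9 without wildtype male 1, 8 without wildtype male 3). With that covariate 5 lists turned direction without passing, namely glycolysis (adjusted p = 0.437), mitochondrially encoded genes (0.525), mitochondrial biogenesis (0.309), fatty acid oxidation (0.819) and proteoglycans (0.0778), and proliferation turned without wildtype male 2 (0.9) and had its lowest adjusted p without wildtype male 3 (5.47e-05). Of 9 lists at 3 months, 0 held with an estimated correlation and 0 with fry (3 to 11; 5 without wildtype female 5, 3 without wildtype male 4), and proteoglycans turned with the block (0.385) and without wildtype female 5 (0.799), with a lowest adjusted p of 4.81e-06 without wildtype male 6. Of 18 lists for age in wildtype, 1 held with an estimated correlation and 9 with fry (17 to 20). The muscle covariate ended 6 of these calls, and 761 of the 1657 genes stayed called with it. The muscle list itself was left out of every list test with that covariate, at 1 month as well. No named gene turned direction while called.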

Other observations

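Slc7a11, Grem1 and Nell2 were among the largest falls from 1 to 3 months in both genotypes, beside the collagens. Slc7a11 imports cystine and Grem1 binds BMPs, and Asns, which makes asparagine, fell in wildtype as well (-1.61 ± 0.23). Whether this reflects less matrix synthesis per cell or fewer matrix-producing cells is open, since the tendon markers other than collagens moved by a median of -1.029.

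C7, a complement component, was higher in males with a log2 fold change of 3.90 ± 0.35. Cpt1a was lower in cKO at 1 month (-0.74 ± 0.21, not passing) while 17 of the 20 fatty acid oxidation genes were positive, and it fell in wildtype between ages (-0.76 ± 0.22). In both comparisons its sign was opposite to that of the muscle markers. Whether a change of tissue content alone would give this was not tested.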
